A study of Homo sapiens with 4 samples.

How the data were processed

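Replication timing was measured in MRC5 fibroblasts on 2-colour Agilent arrays, with 2 arrays of control cells and 2 of cells that stably overexpress PolQ. Per the labels' protocols, cells took up BrdU at 50 µM for 1 h, 80000 cells were sorted into an early and a late S-phase fraction, the BrdU-containing DNA was immunoprecipitated and amplified over the whole genome, and early DNA was labelled with Cy3 and late DNA with Cy5. The dyes were not swapped on any array, so a dye effect stays in each ratio. It cancels in differences between groups only if it was the same on every array, which was not tested. Groups and replicate numbers came from the labels.

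The deposited files hold 1 array each, as output of Agilent Feature Extraction. Its version is 11.5.1.1 per the file headers and 9.1 per the submitters' processing notes. Positions are on build hg19, per the file headers. The processed signals used here are spot intensity values on a linear scale that the software had background-subtracted, detrended over the array and dye-normalized by a linear factor, per the file headers. The deposited log ratio is the log10 of red over green processed signal, per the file headers, and it was only used as a check: it differed by over 0.001 from the ratio of the processed signals at 0.306% to 0.623% of spots. The median and background signals are also deposited intensity values and served an alternative. All 4 arrays came from 1 slide and 1 scan, so slide and scan could not differ between groups.

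Each array held 180880 spots, of which 6546 control spots were left out. Spots with an outlier flag were left out on their array (101 to 212 spots per array), and saturated spots were kept. The log2 ratio of green over red processed signal, early over late, was averaged over spots of a probe. Each array was centred on the median of its autosomal probes, with no loess, quantile or scale normalization, since many positions may truly shift. The 161068 autosomal probes measured on all 4 arrays were averaged in 12244 bins of 200 kb that held at least 5 probes, with a median of 14 probes per bin. Chromosome Y was left out throughout, and X entered 1 alternative only.

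The groups were compared with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, on bins, on probes and on the means of the 22 autosomes, with Benjamini-Hochberg adjustment and a threshold of 0.05. For the 22 chromosomes, limma's prior gave all of them the same standard error. Called bins of one direction at most 1 bin apart were merged, and a region needed at least 2 called bins. A bin changed sides if it was called and above 0 on both arrays of one group and below 0 on both of the other. Timing classes were terciles of bins by the mean of all 4 arrays or of the control arrays. Per-array summaries were compared with an exact permutation test over the 6 assignments of arrays, whose smallest p is 0.333. The rule for named regions, fixed before the data were examined, took the 5 regions per direction with the largest mean difference among the merged regions.

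The fit was tested on simulated data at the real probe positions. For the comparison of PolQ-overexpressing with control arrays, 69.0% of simulated bin shifts of 0.5 and 96.0% of shifts of 1 were recovered among 12244 bins, and 5.17% of calls were false. Among 161068 probes, 62.5% of simulated shifts of 1 were recovered. In the simulation 100 bins were shifted at each size, and noise was drawn independently for each probe and array. The real arrays had far more called bins and shared probe-specific signal within groups, so these shares need not hold for them.

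Alternatives changed the normalization, background correction, filters, bin width, variance prior, array centring and replicates used. They also included a fit with the replicate number as a block. Figures were drawn with matplotlib 3.10.9. The files used here pair probes with positions but not with gene names, and the gene table at hand is on another build (GRCh38). Planned comparisons by gene and gene list, including PolQ's own gene and the protocol's early and late control loci, were therefore not analysed here.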

Results

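Replication timing was measured on 4 arrays of DNA from MRC5 cells, an established human fetal lung fibroblast line. The 2 control arrays and the 2 arrays of cells stably overexpressing PolQ were biological replicates per the series design. The labels do not say whether the overexpressing replicates came from separate clones or transfections, so the spread between replicates may leave out differences between clones. PolQ is DNA polymerase theta, an enzyme known for end joining of broken DNA. On each array, newly made DNA of early S phase carried Cy3 and newly made DNA of late S phase carried Cy5. A higher log2 ratio of early over late signal therefore stands for earlier replication. All positions refer to human genome build hg19. In the early channel, between 79.6% and 82.8% of spots lay well above background on an array, and in the late channel between 94.0% and 95.1%. With 2 arrays per group, the number of arrays limits the precision of every value.

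The first question was how alike the timing profiles were within and between the groups. Across 12244 autosomal bins of 200 kb, the control arrays correlated with each other at r = 0.974 and the PolQ-overexpressing arrays at r = 0.985. The 4 pairs of arrays from different groups correlated less closely, at r = 0.795 to 0.804. Neighbouring bins are not independent, so these correlations are given as values without a test. Bins with a ratio above the array median of the probes made up 47.3% ± 0.202 of bins in control cells and 45.9% ± 0.0751 in PolQ-overexpressing cells (SD, n = 2 each). Large parts of the genome kept their side of that median. Of all bins, 37.2% were early on all 4 arrays and 42.8% were late on all 4.

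**Figure D1:**
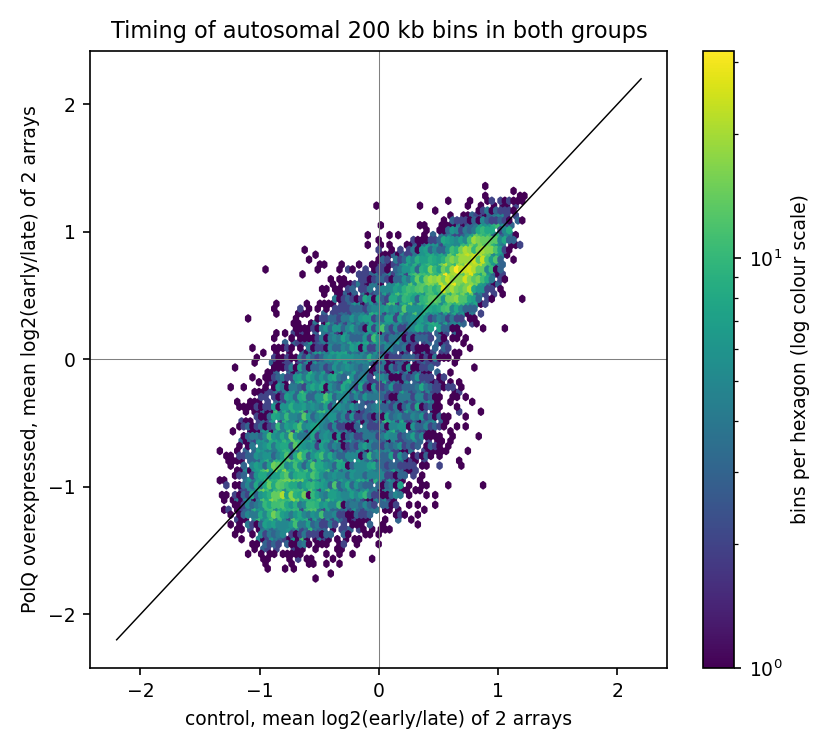
Mean log2 ratio of early over late signal of each 200 kb bin in control cells (x axis) and PolQ-overexpressing cells (y axis), 2 arrays each; colour gives bins per hexagon and the diagonal marks equal values. Bins early in both groups (37.2%) cluster near the diagonal at upper right, and the 12244 bins scatter more widely around it at intermediate and late values.

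The comparison the design implies asks whether PolQ overexpression changed where and when DNA replicated. Of the 12244 bins, 7194 (58.8%) differed between the groups at an adjusted p under 0.05 in limma. This p weighs a difference against the spread between replicate arrays alone, which may leave out differences between clones, sorting or amplification. In PolQ-overexpressing cells 3099 bins replicated earlier and 4095 replicated later than in control cells. Differences of at least 0.5 on the log2 scale were fewer, at 3010 bins, of which 853 moved earlier and 2157 moved later. The split by direction depends on the zero point of each array and on the probes per bin. With arrays centred on the mean of their bins instead of the probe median, 55.2% of called bins were earlier, against 43.1% in the main setting. With at least 10 probes per bin, 2806 bins were earlier and 2622 later. Under each of 5 normalizations, 5012 bins (40.9%) were called in one and the same direction, 2191 earlier and 2821 later.

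Merged over neighbouring bins, the changed bins made 702 regions that replicated earlier, covering 601.2 Mb, and 682 regions that replicated later, covering 836.8 Mb. The median length was 0.6 Mb for earlier regions and 0.8 Mb for later regions, and 419 of the 1384 regions were over 1 Mb. The longest later region spanned 7 Mb of the long arm of chromosome 6, from 63800001 to 70800000, where the ratio over all its bins fell from -0.13 ± 0.05 in control cells to -0.86 ± 0.03 in PolQ-overexpressing cells (SD, n = 2 each). A later region of 6.4 Mb lay on the short arm of chromosome 3, from 73400001 to 79800000, with a ratio of -0.27 ± 0.01 in control cells and -0.91 ± 0.04 in PolQ-overexpressing cells. Another of 6.4 Mb lay on the short arm of chromosome 5, from 19400001 to 25800000, with -0.13 ± 0.02 against -0.80 ± 0.01. The longest earlier region covered 4.2 Mb of the long arm of chromosome 14, from 93400001 to 97600000, where the ratio went from -0.42 ± 0.03 to -0.01 ± 0.01. These long regions were chosen by length after the values were seen.

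The 5 regions with the largest mean shift towards earlier replication were taken by a rule fixed before the data were examined. The largest lay on the long arm of chromosome 4, from 112800001 to 114000000. Its ratio was -0.69 ± 0.06 in control cells and 0.34 ± 0.01 in PolQ-overexpressing cells, a difference of 1.03 over 83 probes (SD, n = 2 each), and each of its called bins had an adjusted p of 0.00995 or lower in limma. On chromosome 8, the region from 88600001 to 89400000 moved from -0.78 ± 0.04 to 0.16 ± 0.02, and the region from 142400001 to 144200000 moved from -0.61 ± 0.05 to 0.18 ± 0.03. The region of chromosome 14 from 104200001 to 105000000 moved from -0.27 ± 0.05 to 0.57 ± 0.01. The region of chromosome 12 from 87600001 to 89400000 moved from -0.28 ± 0.01 to 0.50 ± 0.01. All 5 were late in control cells and early in PolQ-overexpressing cells relative to the array median.

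The 5 regions with the largest shift towards later replication were taken by the same rule. The largest lay on the short arm of chromosome 5, from 17800001 to 19000000, where the ratio was 0.11 ± 0.04 in control cells and -1.08 ± 0.10 in PolQ-overexpressing cells, a difference of -1.18 over 28 probes (SD, n = 2 each). Each of its called bins had an adjusted p of 0.000914 or lower in limma. The region of chromosome 3 from 103600001 to 104000000 was late in both groups and moved from -0.14 ± 0.09 to -1.24 ± 0.11. On chromosome 8, the region from 115600001 to 116000000 moved from 0.09 ± 0.04 to -0.996 ± 0.08, and the region from 113200001 to 115000000 moved from 0.22 ± 0.03 to -0.84 ± 0.04. The region of chromosome 4 from 132000001 to 132400000 moved from 0.51 ± 0.13 to -0.57 ± 0.19. In all 10 regions the group means differed by more than the SD between replicate arrays. The regions were picked for large differences called on these same arrays, so this follows from the choice. Their sizes may be overstated for the same reason. Between 12 and 117 probes lay behind each region. Normexp background correction added an offset of 50 to both channels, which by itself shrinks log ratios. After it the differences of the 5 earlier regions were 0.45 to 0.62 and those of the 5 later regions -0.84 to -0.31. Of the 10 regions, 6 moved by over 1.5 times. With at least 10 probes per bin, 4 of the later regions held no bin to test, and the region of chromosome 8 from 88600001 differed by 0.56. The genes in these regions were not analysed here.

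**Figure D2:**
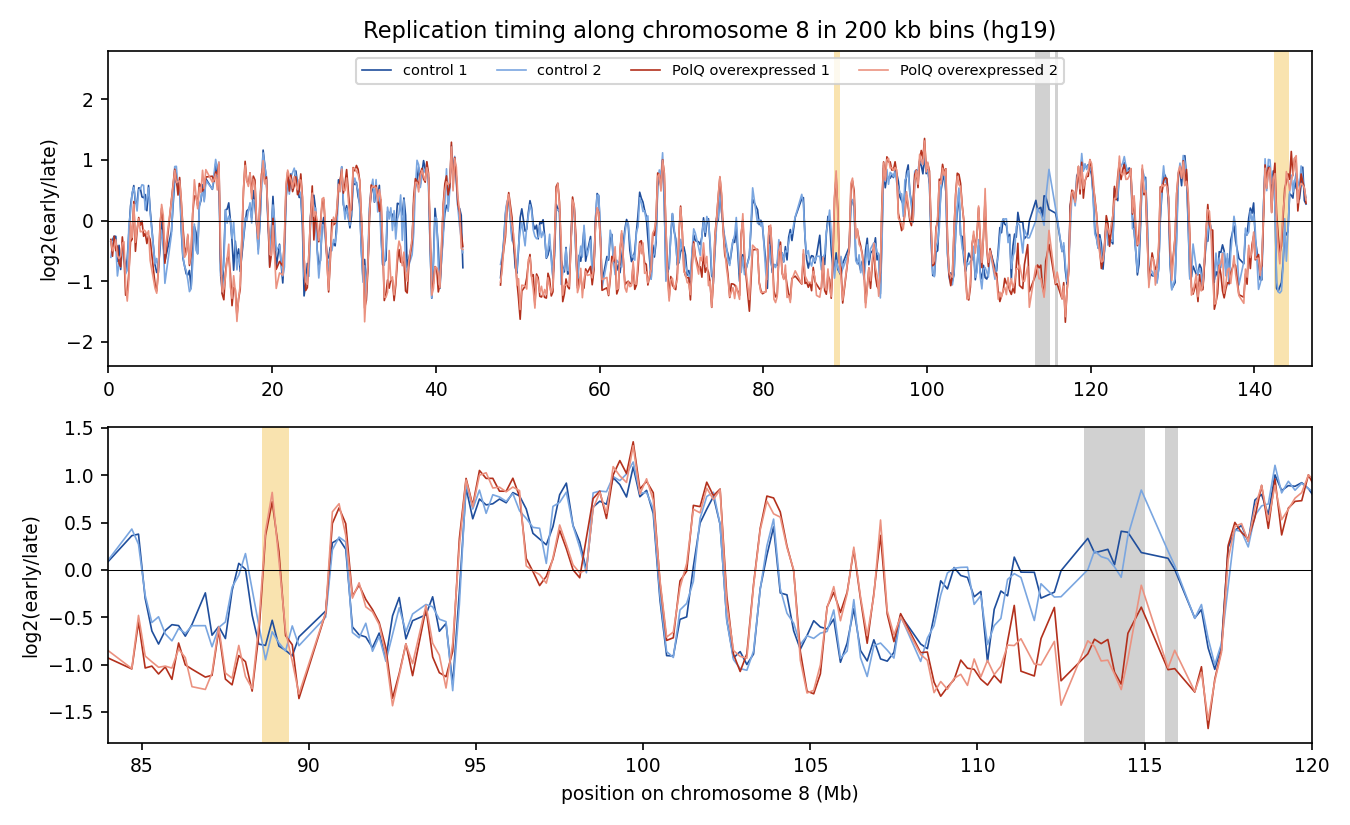
Log2 ratio of early over late signal (y axis) in 200 kb bins along chromosome 8 in Mb (x axis, upper panel the whole chromosome, lower panel an enlarged part), with 1 line per array; bands mark the named earlier (yellow) and later (grey) regions. Replicate lines run together, while at 88.6 to 89.4 Mb the PolQ-overexpressing arrays rise to a mean of 0.16 against -0.78 in control cells.

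A smaller set of bins changed sides. Relative to the array median, 1551 bins (12.7%) passed the test and were early on both arrays of one group and late on both arrays of the other. Of these, 833 bins (166.6 Mb) were early in control cells and late in PolQ-overexpressing cells, and 718 bins (143.6 Mb) were late in control cells and early in PolQ-overexpressing cells. The longest stretch that went from early to late spanned 3.2 Mb of chromosome 2, from 76800001 to 80000000, with a mean difference of -0.90. The longest stretches from late to early spanned 1.4 Mb each, on chromosome 3 from 125800001 to 127200000 with a mean difference of 0.42 and on chromosome 9 from 135400001 to 136800000 with 0.71. The balance between the directions turned with the filter on probes. With only probes well above background on every array, 351 bins went from early to late and 578 from late to early, and with at least 10 probes per bin 450 and 620 did. These settings tested 10099 and 9151 bins in place of 12244, so part of the change may come from the bins left out.

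Bins of all timing classes changed, most often those of intermediate timing. Among the 4081 bins in the middle tercile of control timing, 1343 moved earlier and 1806 moved later. In the earliest tercile 618 moved earlier and 846 moved later, and in the latest tercile 1138 moved earlier and 1443 moved later. With these terciles of control timing, the mean ratio of the earliest tercile was 0.66 ± 0.02 in control cells and 0.61 ± 0.01 in PolQ-overexpressing cells, that of the middle tercile -0.06 ± 0.0046 against -0.23 ± 0.0041, and that of the latest tercile -0.74 ± 0.01 against -0.78 ± 0.01 (SD, n = 2 each). Terciles were also set by the mean of all 4 arrays, as planned. The mean ratio of the latest tercile was then -0.68 ± 0.01 in control cells and -0.94 ± 0.01 in PolQ-overexpressing cells. That of the middle tercile was -0.098 ± 0.0014 against -0.157 ± 0.0035, and that of the earliest 0.64 ± 0.02 against 0.69 ± 0.01 (SD, n = 2 each). The earliest of these terciles had 983 bins earlier and 496 later, the middle 1557 and 1448, and the latest 559 and 2151. The size and direction of the shifts, and the balance of the counts, thus depend on which arrays set the terciles. Bins that differ strongly between groups also tend towards the middle of the mean of all 4 arrays. The high count of changed bins in that middle tercile may partly follow from this. With all 4 arrays the shift of the earliest tercile was 0.055, and with each array left out in turn it ranged from 0.031 without PolQ-overexpressing replicate 1 to 0.088 without control replicate 2. That of the latest tercile was -0.252 with all 4 arrays and ranged from -0.327 to -0.166, the latter without PolQ-overexpressing replicate 1. With an array left out, terciles were set anew from the arrays kept, so these ranges also reflect other bins in each class. In the latest tercile set by all 4 arrays, the control arrays averaged -0.676 and -0.690. The PolQ-overexpressing arrays averaged -0.942 and -0.928 there. With terciles from all 4 arrays, the shift of the earliest tercile also turned to -0.11 and that of the latest changed from -0.25 to -0.028 when arrays were scaled to a common median absolute deviation. The exact permutation test over the arrays gave p = 0.333 for each tercile, two-sided, the smallest p this test allows with 2 against 2 arrays, so it cannot reach 0.05.

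**Figure D3:**
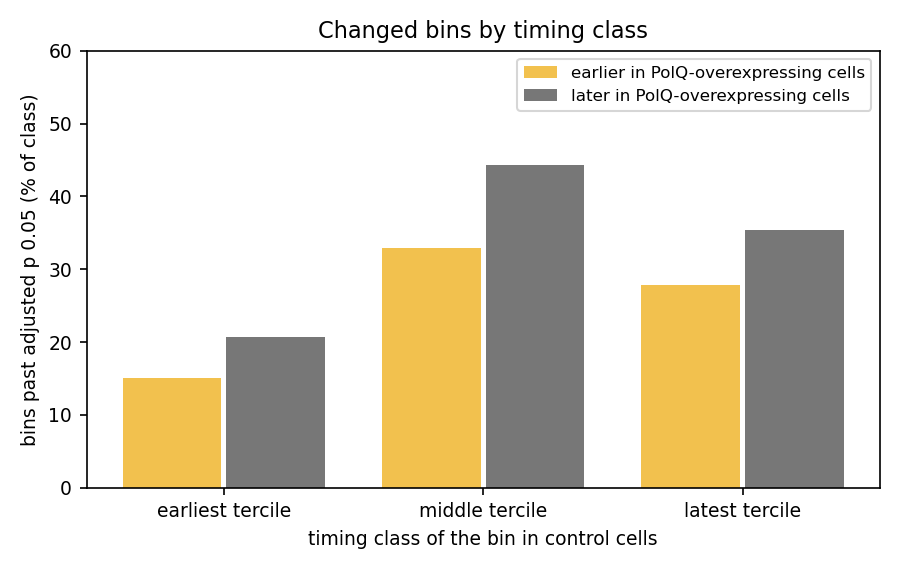
Share of bins in each tercile of control timing (x axis) that replicated earlier (yellow) or later (grey) in PolQ-overexpressing cells at an adjusted p under 0.05 in limma (y axis, percent of the tercile). With these terciles the middle one has the highest shares, 32.9% earlier and 44.3% later. With terciles by the mean of all 4 arrays, the latest one has the highest later share, 52.7%.

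The range of timing values was wider in PolQ-overexpressing cells. The SD of the ratio across bins was 0.610 ± 0.0134 in control cells and 0.734 ± 0.00817 in PolQ-overexpressing cells (SD, n = 2 each), a ratio of 1.20. The difference exceeded the spread between replicate arrays, but the exact permutation test gave p = 0.333, two-sided, again the smallest this test allows. With arrays scaled to a common median absolute deviation, the difference in SD turned from 0.124 to -0.0377.

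Whole chromosomes shifted to different extents. In the main setting, chromosomes 4, 18 and 21 shifted furthest towards later replication, by -0.20, -0.18 and -0.17 on the log2 scale, with a standard error of 0.01 each. Chromosome 22 shifted earlier by 0.08 and chromosome 19 by 0.06, and chromosome 17 by 0.023. These 6 chromosomes were chosen after their values were seen. All 22 autosomes passed an adjusted p of 0.05 in limma, 3 earlier and 19 later. Those p-values rest on the spread between replicate arrays, which may leave out differences between clones or preparations. The shifts are relative to each array's probe median, and the mean difference over all bins was -0.09. After normexp background correction 15 chromosomes passed, 2 earlier and 13 later, and after quantile normalization 18 passed, 6 earlier and 12 later. Centred on the mean of the bins, 11 chromosomes passed as earlier and 8 as later. Chromosomes 4, 18 and 21 stayed later and chromosome 22 stayed earlier under the 13 alternatives that gave chromosome values. Chromosomes were not compared with other bin widths, with at least 10 probes per bin or with X included. Their sizes did not hold: chromosome 4 was at -0.062 with only probes well above background, chromosome 18 at -0.061 after normexp, chromosome 21 at -0.083 with bin-mean centring and chromosome 22 at 0.015 with scaled arrays. Chromosome 17 no longer passed without control replicate 1 (0.0074), without PolQ-overexpressing replicate 1 (0.021), after normexp (0.012, adjusted p = 0.546 in limma) or with the replicate number as a block (adjusted p = 0.136 in limma). It turned to -0.042 with scaled arrays and to -0.058 with only probes well above background, and chromosome 19 turned to -0.0094 with only probes well above background. The brightness of both channels together also differed by chromosome, and was lower in PolQ-overexpressing cells on chromosomes 17, 19 and 22 (-0.36, -0.34 and -0.28, log2) and higher on chromosomes 4 and 21 (0.14 and 0.37), while chromosome 18 was lower (-0.14).

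**Figure D4:**
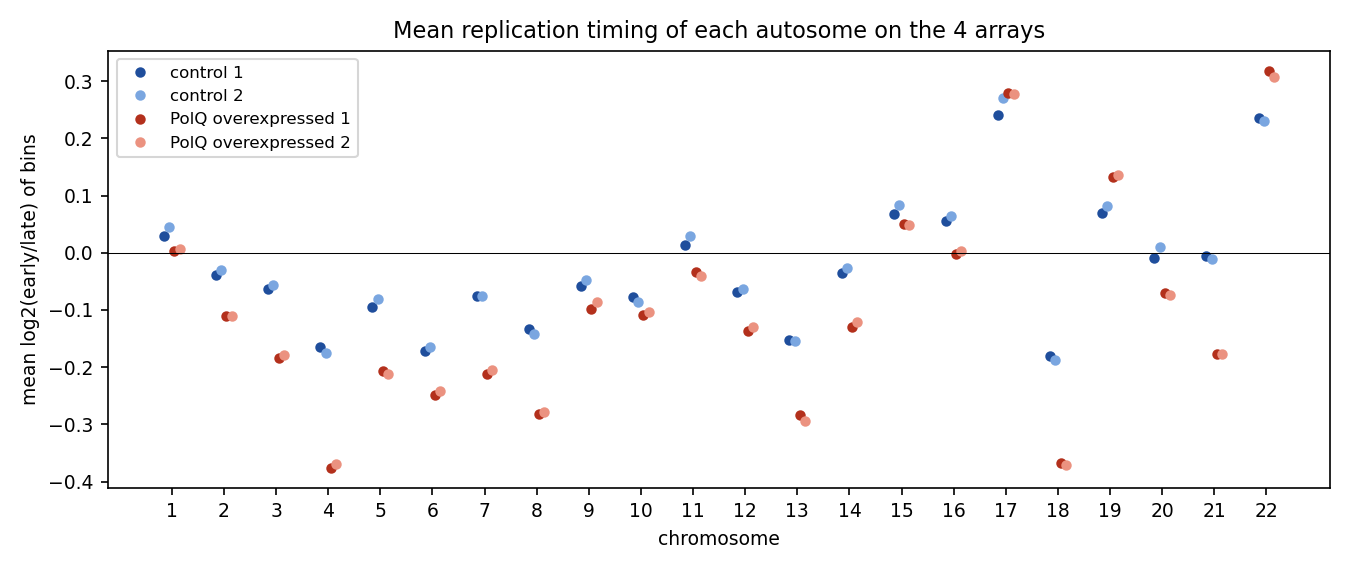
Mean log2 ratio of early over late signal over the bins of each autosome (y axis) by chromosome (x axis), with 1 point per array. On chromosome 4 the control arrays average -0.17 and the PolQ-overexpressing arrays -0.37.

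Single probes carried less certain differences than bins. Of 161068 autosomal probes, 21412 (13.3%) passed an adjusted p of 0.05 in limma, 9899 earlier and 11513 later. After normexp 41729 probes passed, with only probes well above background 38061, and with the replicate number as a block 0. With any one array left out, 0 probes passed in limma, with 42371 to 47417 probes at an unadjusted p under 0.05.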

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

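Scaling the arrays and keeping only probes well above background were planned settings, and the other tests in this part were chosen after the results they bear on had been seen. The brightness of both channels together, which the comparisons of timing do not use, differed between the groups on all 22 autosomes in limma, by over 0.2 (log2) on 10 of them, and moved in steps along some. Boundaries were placed on the replicate 1 arrays and step sizes were taken from the replicate 2 arrays, over 25 bins on either side. Steps over 0.6 (log2, PolQ-overexpressing minus control) appeared on 4 of 22 chromosomes and exceeded the step between the control arrays, at most 0.115 there. At 120000000 on chromosome 12 the step was -0.64, at 68000000 on chromosome 13 it was -0.69, at 101600000 on chromosome 14 it was -0.81, and at 9800000 on chromosome 18 it was 1.00.

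A difference in copy number between the cells would move both channels alike and leave their ratio nearly level. The 4 steps over 0.6 were picked for their size in both channels. There the median size of the step of the early over late ratio, with signs left out, was 0.0928 of the channel step. Over the boundaries on all 22 chromosomes the same median was 0.404. Copy number cannot be told apart from other causes at the 4 steps over 0.6. No single step of the ratio was bounded under 0.5 of the channel step by 2 standard errors. These errors (0.220 to 0.292 for a step of the ratio) allow for the correlation of neighbouring bins. On chromosome 13 the share was 0.389 in size, and the ratio rose by 0.27 where the channels fell. A share weighted over the 4 steps with signs kept, calculated after the single steps had been seen, was -0.0996 with a standard error of 0.162. An amplification trend following timing or probe density cannot be told apart either: 76.4% to 99.6% of each step was left once the timing of both groups and probe density were fitted, over 0.5 of it by 2 standard errors on chromosomes 12 and 14 but not on chromosomes 13 and 18. A trend with GC content was not tested, and a change brought by PolQ itself stays open.

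The second pattern is that 58.8% of bins differed between groups whose replicates correlated at 0.974 or higher. A wider range on the PolQ-overexpressing arrays is argued against as the whole cause, since 79.9% of the called bins kept their call and direction after scaling. A difference in brightness was not needed for a call, as 56.8% of bins were still called where both channels together differed by under 0.1. Brightness was centred on each array and copy number was not measured, so equal brightness need not mean equal copy number. A copy-number difference would by itself leave the ratio nearly level, so a share close to the 58.8% of all bins was likely beforehand. No conclusion about copy number is drawn from it. Probe-specific signal shared within groups made up only 7.37% of the variance of bin differences. Sorting or amplification shared by the arrays of a group cannot be told apart from PolQ overexpression, because the labels give no sorting or amplification batches. A difference between clones was not tested. That preparations may matter is seen in the probe-specific covariance, 0.0760 higher within than between groups, so an effect of PolQ is one of the open explanations. This covariance was 0.0752 for the control pair, 0.156 for the PolQ-overexpressing pair and 0.0394 on average between groups.

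The third pattern is the wider range of ratios on the PolQ-overexpressing arrays. With only probes well above background on every array, a difference of 0.0736 was left. For the probes kept, this argues against signal near background in control arrays as the whole cause. That setting tested 10099 bins in place of 12244. The drop from 0.124 over all probes therefore cannot be assigned to background alone. One factor on all ratios cannot be told apart from other causes, because the values go both ways. With arrays scaled to one median absolute deviation the SDs of the bins still differed, by -0.0377, beyond the SD of 0.0111 between replicate arrays, whereas the SD of differences between neighbouring probes rose 1.20 times, as the SD of the bins did. Sharper sorting and a biological change in PolQ-overexpressing cells may both remain, and neither was tested.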

How the results depend on the processing

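Centring on the bin mean and the restriction to bins of equal brightness were chosen after seeing the data; all other settings were planned. The 10 named regions kept their direction and call in all 163 values computed under alternatives, but not their size: 6 moved by over 1.5 times after normexp, to as little as -0.31 on chromosome 4 from 132000001, and 1 with at least 10 probes per bin. There 4 regions gave no value, and 3 gave none with only probes well above background. The regions were picked as the largest called differences on these arrays, so keeping direction and call was likely beforehand. Changing the variance prior or adding the replicate block leaves their size as it was. A region counted as called here if the median adjusted p of its bins in limma was under 0.05. Bins passing the test numbered 7043 to 7540 under the other normalizations and background correction, and 5926 to 6459 with each array left out, where a lone array is assumed to vary like the other group. Counts that moved because other bins were tested were 10972 of 22947 bins of 100 kb, 3716 of 5333 bins of 500 kb and 1415 of 2491 bins of equal brightness. Requiring a difference of 0.5 left 3010. With at least 10 probes per bin, 2806 bins were earlier and 2622 later, the reverse of the main balance. Regions fell to 749 with 500 kb bins. The setting with only probes well above background tested 10099 bins, and that with at least 10 probes per bin tested 9151. Bins changing sides numbered 2563 with 100 kb bins, 746 with 500 kb bins and 929 with only probes well above background, of which 351 went from early to late and 578 from late to early; with at least 10 probes per bin these were 450 and 620. Probes passing numbered 41729 after normexp and 38061 with only probes well above background, against 0 with any array left out, a range of 0 to 0. The causes of the moves below were not tested.

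With the replicate number as a block, 7137 bins passed, 6942 of them shared with the main fit, while 0 probes passed in limma (53898 at an unadjusted p under 0.05) and chromosome 17 no longer passed (adjusted p = 0.136 in limma, replicate block, at 0.023). The deviations of same-numbered arrays correlated at -0.0343, so the numbers were not taken as pairing the arrays.

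The difference in SD across bins was -0.0377 with scaled arrays, 0.00825 after quantile normalization, 0.110 after loess, 0.0639 after normexp, 0.0736 with only probes well above background and 0.0940 with at least 10 probes per bin. The shift of the earliest tercile was -0.113 with scaled arrays, -0.0077 after quantile normalization, 0.0098 after normexp, -0.057 with only probes well above background, 0.034 with at least 10 probes per bin and 0.140 with bin-mean centring. With terciles from one control array and the difference taken against the other, it was -0.069 and -0.029. For the middle tercile the same 6 settings gave, in that order, -0.054, -0.031, -0.035, 0.042, 0.090 and 0.027, with loess at -0.066, 100 kb bins at -0.028, 500 kb bins at -0.120, X included at -0.082, and -0.162 with terciles from either control array. For the latest tercile they gave -0.028, -0.031, -0.152, -0.217, -0.174 and -0.167, with loess at -0.229, 100 kb bins at -0.242, 500 kb bins at -0.271, and -0.035 and -0.056 with terciles from a control array. With each array left out, terciles were set anew from the arrays kept. The shift then ranged from 0.031 to 0.088 for the earliest, from -0.120 to -0.0041 for the middle and from -0.327 to -0.166 for the latest tercile.

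Of 286 chromosome values under alternatives, 251 kept direction and call, 13 lost the call and 22 reversed, on 13 chromosomes. Of the 22 reversals, 10 came from bin-mean centring, by construction of the zero point. No chromosome values were computed with other bin widths, at least 10 probes per bin or X included. Among the named chromosomes, chromosome 17 reversed to -0.042 with scaled arrays and to -0.058 with only probes well above background, where chromosome 19 reversed to -0.0094. The mean correlation between groups was 0.815 after loess, 0.822 after normexp, 0.853 with only probes well above background, 0.783 with 100 kb bins, 0.830 with at least 10 probes per bin and 0.792 with X included. Within groups it was 0.991 with only probes well above background, 0.965 with 100 kb bins and 0.989 with 500 kb bins.

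A correction for GC content, slide or scan as a block, and gene windows were not run: no probe sequence, a single slide and no gene names were at hand. Normexp used the median signals and added an offset of 50 to both channels. The offset by itself shrinks log ratios, so smaller differences after normexp need not come from the background correction. Signal over background limits the early channel most, where 79.6% to 82.8% of spots lay well above it.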

Other observations

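The number of timing domains, counted as runs of one sign in a profile averaged over 3 bins, was 1485 and 1473 on the control arrays and 1133 and 1121 on the PolQ-overexpressing arrays. The median late domain was 1.4 Mb long on both control arrays and 1.6 Mb on both PolQ-overexpressing arrays. Late domains over 5 Mb numbered 33 and 34 on the control arrays and 65 and 69 on the PolQ-overexpressing arrays. Early domains over 5 Mb numbered 27 and 26 against 39 and 39. The sign was taken about each array's probe median, and the median bin lay at -0.065 and -0.066 on the control arrays. On the PolQ-overexpressing arrays it lay at -0.158 and -0.152. Domains were not counted with another centring, so their numbers and lengths may depend on the zero point. Lengths count bins in order, so they leave out missing bins and can run across gaps in the probes.

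The difference between the groups was smooth along the genome. Across 11474 pairs of neighbouring bins it correlated at 0.770 with the next bin, while the difference between the control arrays did so at 0.0258 and that between the PolQ-overexpressing arrays at 0.00382. The spread behind the limma p-values thus held little variation that is smooth along the genome. Called bins and chromosomes differ beyond that spread, but need not differ beyond variation between clones or preparations.

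Both tests of hypotheses below were chosen after the pattern was seen, and GC content was not tested in either. A first hypothesis is that chromosome ends moved earlier than the interior. Bins within 5 Mb of the outermost bins lay 0.14 higher in their difference than the rest (0.05 against -0.10). The first 5 Mb of bins on each acrocentric chromosome were counted with the rest. A permutation test over 10000 circular shifts of the genome gave p = 0.0020, two-sided. With timing and probe density fitted the excess was 0.079 (permutation over circular shifts, p = 0.0213), so part of it may follow those.

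A second hypothesis is that sequence with few probes moved later. The 3093 bins with 5 to 9 probes had a mean difference of -0.29, and 53.4% of them were called later, while bins with 10 to 14, 15 to 16 and 17 to 30 probes had mean differences of -0.039, -0.0042 and 0.0070. The mean of bins with 5 to 9 probes minus that of the rest was -0.273 (permutation over circular shifts, two-sided, p = 1e-04, the smallest these shifts can give). With scaled arrays the means were -0.196, -0.0148, -0.0176 and -0.0329 in that order and the gap was -0.176, so the wider range on PolQ-overexpressing arrays may account for part of it. With timing fitted the gap was -0.186. Across all bins, probes per bin and the difference correlated at a Spearman rho of 0.243, or 0.127 with scaled arrays.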
